A study of Mus musculus with 4 samples.

How the data were processed

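Gene expression was measured in mouse embryos at the early headfold stage that carried a GFP insertion in Noto, a homeobox gene of the node and notochord. Per the labels' protocols, the node-containing distal piece of each embryo was cut off and pooled with 120 to 150 others, total RNA was extracted with a DNase step, and labelled complementary RNA of a homozygous pool (Noto GFP/GFP) and of a heterozygous pool (Noto GFP/+) was hybridised together on 1 Agilent 2-colour array. The fields of the labels differ on how large the distal piece was. A second array repeated the hybridisation with the dyes exchanged, as a technical replicate per the labels. The 4 samples are therefore 2 arrays with both genotypes on each: on array 1 the homozygote carried Cy5 and on array 2 Cy3. The scanner files of the paired samples of an array held identical bytes, so each array was read once. The 2 arrays lay on different slides and were scanned on different days, and each held both genotypes.

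Per the file headers, the authors scanned the arrays and read them with Agilent Feature Extraction (version 9.5.3.1, also given in the submitters' processing notes), which wrote the foreground and background intensity of each spot, a background-subtracted and dye-normalized processed intensity for each dye, and a log10 ratio of red over green. The authors also deposited a value table with 1 column per sample. Set against the scanner files, each of its columns was 1.07 (array 1) or 1.28 (array 2) times the processed intensity of the dye that the label names, floored at 15, with column medians of 109.6 and 110.6 on array 1 and 95.1 and 96.2 on array 2. The SD of the log2 ratio between a column and its own dye lay between 0.0054 and 0.064, against 0.36 to 0.40 for the other dye. Each column thus follows the dye that its label names, which does not check the genotype that the label names. The method behind the constant factors is unstated. The flags for spots well above background, saturated or outlying (unit other in the record of columns) were also deposited per the file headers.

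Each array held 45018 spots, of which 43379 belonged to genes and 1639 were controls. The median gene spot had foreground intensities of 305 (Cy3) and 438 (Cy5) over backgrounds of 45.5 and 57 on array 1, and of 399.6 and 722 over 64.5 and 67 on array 2. On array 1, 77.7% of the Cy3 and 81.5% of the Cy5 gene spots were well above background, and on array 2 64.0% and 68.1%. No gene spot was saturated (0 on each array). The scanner software's own summary of spiked-in control RNAs gave slopes of observed on expected log ratio of 0.809 and 0.705 on the 2 arrays, with a correlation of 0.991 and 0.990, so ratios were compressed. The number of arrays limits the precision.

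From the mean foreground and median local background intensities, limma 3.58.1 in R 4.3.3 applied normexp background correction with an offset of 50, then loess within each array with control spots at weight 0. Spots that the software marked as outliers (179 and 165) were left out. Array 2 was turned so that both log2 ratios read homozygote over heterozygote. Spots of 1 probe were averaged, which left 41174 probes. A probe counted as measured if it was well above background in at least 1 genotype on both arrays, and a gene took the value of its brightest measured probe. A gene dim on both arrays in 1 genotype only would be given as a bound of at least N-fold, computed on loess and Aquantile levels; no gene named here needed one. Gene names came from the files' accessions and names, updated through a RefSeq table (assembly GRCm38.p6, used for names and neighbours only): 33116 probes matched and 8058 kept the name in the file. Positions are those of the probes in the files, on mouse build mm8. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 gave the summaries and plots.

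With 1 RNA pool per genotype there are no biological replicates, so no significance test was made and no p-value is given. Values are the mean of the 2 log2 ratios ± their SD over the 2 arrays, which measures technical spread only. A gene is called higher or lower when its ratio is at least 1.5-fold (0.58 on the log2 scale) in the same direction on each array. The same rule with array 2 left unturned counts genes that follow the dye. For 23 gene lists and the neighbours of Noto, the median log2 ratio was set among the medians of 10000 random lists of the same size matched on mean brightness in 20 bins, as a description of these arrays; the SD beside it is that of the medians on each array. The rules, lists and most alternatives were chosen before the data were examined. Genes are named by a fixed rule: Noto, up to 12 of the largest ratios in each direction among called genes with a real symbol, up to 4 called members of each list by size (with fewer than 2, the 2 measured members farthest from 0 are given as values), and 11 regulators given whatever their values. A few values that the rule would give are not reported here. Pkd1l1 was not well above background and has no value. The list of chromosome 6 neighbours was to be centred on the Noto probe; since Noto itself was not analysed here, the point midway between the probes of its neighbours Smyd5 and Cct7 was used, with windows of 5 and 20 Mb. Hbb-b1 of the blood list is now named Hbb-bt in the table and is given apart from that list.

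The alternatives were no background correction, the software's processed log ratios, the value table, median centring without loess, the mean of measured probes, each array alone, no filter and a stricter filter on dim probes, 2-fold rules, and lists without their farthest member. Counts and lists among the genes brighter than the median of the measured genes, and counts without unnamed transcripts and 5 tissue-specific gene families, were added after seeing the data. The calls were tested on simulated data: scans of the same spots with a dye trend, noise of the size seen between the arrays and 199 changed probes among 27750. All of the 49 probes changed by 2-fold, the 50 by 3-fold and the 50 by 4-fold were called the right way, against 12 of the 50 changed by 1.5-fold, and 0 of 27551 unchanged probes were called. The changed probes were drawn only from those well above background in both dyes on both arrays. The noise had the same SD at every brightness and was independent between the arrays. These rates therefore do not cover the calls of dim genes. In a separate check on the measured values themselves, 2.5% of 200 unshifted random lists of 40 genes fell below percentile 2.5. That share follows from drawing the lists at random from the genes they are ranked among, so it does not cover lists of co-regulated genes. After a shift of 0.3, larger than any list median reported with the main processing, 100% fell below it.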

Results

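Noto is a transcription factor of the mouse node, the left-right organiser, whose pit cells each carry a motile cilium. The series asks which genes act downstream of the ciliogenic factor FOXJ1, and this part compares node-containing distal pieces of embryos homozygous for a GFP insertion in Noto with heterozygous ones at the early headfold stage. One RNA pool of each genotype was measured on 2 arrays with exchanged dyes, so each genotype has 2 samples from 1 pool. Of 41174 gene probes, 27734 were measured, covering 18579 genes. All values are log2 ratios of homozygote over heterozygote, for genes as the mean ± SD over the 2 arrays. For lists, the median of the 2-array means is given ± the SD of the medians on each array. A list value can therefore lie outside its medians on both arrays. Positions are those of the probes on mouse build mm8, and which part of the gene a probe covers was not examined. The SD is technical, and no difference between the genotypes has a biological replicate check. Noto itself was not analysed here, so the targeted gene gives no check of the labels.

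The lists of motile cilium and FOXJ1-linked genes had ratios shifted below 0 in the homozygous pool, with a median of -0.17 and 11 of their 138 measured genes lower. Adult globins and many dim transcripts were lower too, and few genes were higher. By the size rule 437 genes were lower and 11 were higher, 2.41% of those measured. The rule gave 14 genes when array 2 was left unturned (10 higher and 4 lower), and the ratios of the 2 arrays correlated with r = 0.50 across genes, which are not independent replicates. That r was -0.052 with median centring in place of loess, and 0.131 among genes brighter than the median. Of the lower genes, 256 have only an accession, clone, predicted-gene or RIKEN name. The called genes were mostly dim, with 387 dimmer and 61 brighter than the median of the measured genes. Without unnamed transcripts and 5 families of olfactory, vomeronasal, immunoglobulin variable, keratin-associated and Speer genes, a choice made after seeing the data, 140 genes were lower and 8 higher.

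**Figure D1:**
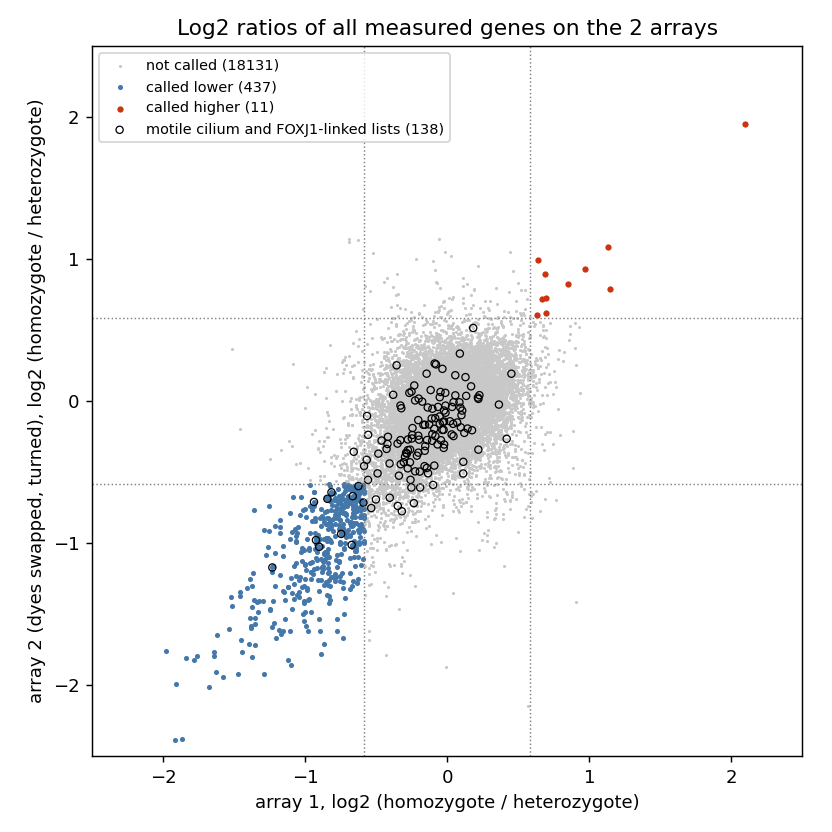
Log2 ratio of homozygote over heterozygote of each of the 18579 measured genes on array 1 (x axis) and on array 2 with its sign turned (y axis); dotted lines mark 1.5-fold and open circles the 138 measured genes of the motile cilium and FOXJ1-linked lists. The 437 lower genes fill the lower left corner, and 11 genes lie at the upper right.

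The higher genes with a real symbol were led by Prl8a2, a prolactin-family hormone of the decidua, at 1.11 ± 0.03. Next came Dcpp3 (0.97 ± 0.25), the carboxylesterase Ces1c (0.83 ± 0.02), the Nodal antagonist Lefty2 (0.82 ± 0.25) and the ubiquitin-conjugating enzyme Ube2s (0.79 ± 0.15). The vitamin E binding protein Afm (0.69 ± 0.04), the histone deacetylase Hdac9 (0.66 ± 0.06) and Cd38 (0.62 ± 0.01) were also higher. For Dcpp3 and Afm the heterozygote was well above background on only 1 of the 2 arrays, and the order depends on the processing. With the software's processed log ratios, Dcpp3 (2.02) and Afm (1.59) exceeded Prl8a2 (1.34). With the value table Dcpp3 did so too (1.62 against 1.31). A second probe read 0.26 for Cd38, which missed the rule with the mean of probes (0.44), and Ube2s, Afm, Hdac9 and Cd38 missed it on 1 array each with median centring. So did Hdac9 and Cd38 with no background correction and Ube2s with the value table. The other 3 higher genes have no real symbol.

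The lowest ratio among genes with a real symbol was that of Mid1, a microtubule-associated ubiquitin ligase on the X chromosome (probe at 165333696 to 165333755), at -2.15 ± 0.33. Fam186b (-1.61 ± 0.45), the copper transporter Atp7b (-1.47 ± 0.49), the zinc finger gene Zfp473 (-1.44 ± 0.32) and Dcaf12l2 (-1.29 ± 0.59) followed. A second measured probe read 0.06 for Mid1, 0.14 for Zfp473 and -0.02 for Dcaf12l2, so the calls of these 3 genes rest on 1 probe. Zfp473 and Dcaf12l2 missed the rule with the mean of probes (-0.65 each), and Dcaf12l2 missed it on array 1 with median centring (-1.11). The multicopy genes Speer5-ps1 (-1.41 ± 0.25), Speer4d (-1.34 ± 0.27), Speer8-ps1 (-1.28 ± 0.38), Speer4cos (-1.22 ± 0.18) and Pramel48 (-1.26 ± 0.51) and the immunoglobulin segment Igh-VJ558 (-1.22 ± 0.37) were lower too, with probes that near-identical copies may share. In the homozygote, Speer4d and Speer8-ps1 were well above background on 1 of the 2 arrays. Across all called genes with at least 2 measured probes (70), every probe passed in 21 and a probe of opposite sign was present in 16. Among genes not called by their brightest probe, 100 had another measured probe that passed.

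All 3 lists of motile cilium and FOXJ1-linked genes had medians below those of nearly all random lists. Radial spoke, central pair, ruler and nexin link genes had a median of -0.28 ± 0.01, below all 10000 random lists; 3 of 48 measured members were lower and 0 higher, and 35 had ratios below 0 on both arrays. These 3 were Dydc2, which encodes a DPY30-domain protein (-1.20 ± 0.04; chromosome 14, 39957861 to 39957920), the axonemal protein gene Cfap45 (-0.73 ± 0.12) and 1700007K13Rik, also named Pierce1, which acts in left-right development (-0.61 ± 0.02). A second, dimmer probe of 1700007K13Rik read -0.18, and the gene missed the rule with the mean of probes (-0.40). FOXJ1-linked and ciliated-cell genes had a median of -0.17 ± 0.07, again below all 10000 random lists, with 7 of 60 members lower and 0 higher. Members that this screen first tied to FOXJ1 would not be independent evidence of the direction. The largest changes were in Fam183b (-0.96 ± 0.09; chromosome 11, 58609032 to 58609091), Fam166b (-0.84 ± 0.24), Meig1 (-0.84 ± 0.13) and Tppp3 (-0.82 ± 0.16). Genes of the dynein arms and their assembly had a median of -0.15 ± 0.07, at percentile 0.14, but of -0.058 at percentile 9.0 among the 10 brighter than the median of all genes, a limit chosen after seeing the data. On array 1 alone it lay at percentile 4.3. Of 30 measured, 1 was lower, the dynein light chain Dynlrb2 (-0.95 ± 0.04; chromosome 8, 119401788 to 119401847), and 0 were higher. A second Dynlrb2 probe also passed, at -0.82. The assembly factor genes Zmynd10 (-0.56 ± 0.00) and Dnaaf1 (-0.50 ± 0.01) missed the rule. With median centring, Dynlrb2 (-0.73), Cfap45 (-0.53), 1700007K13Rik (-0.39) and Fam183b (-0.72) missed the rule, each on array 1. The axonemal dynein Dnah11, which node ciliary beating requires, read 0.17 ± 0.27 and did not differ between genotypes beyond the technical spread.

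Foxj1 read -0.52 ± 0.09 (-0.59 and -0.46 on the 2 arrays; chromosome 11, 116146990 to 116147049), a ratio below 0 on both that missed the rule on array 2. With median centring it read -0.31. Rfx3, the other main regulator of ciliary genes, read 0.02 ± 0.01, and its other probes 0.25 and 0.06. Among the 13 measured ciliogenic regulators 0 were called, and their median was 0.02 ± 0.03 at percentile 71.0; Foxj1 and Deup1 (0.30 ± 0.33) lay farthest from 0. The genes shared by motile and immotile cilia showed no such shift. Intraflagellar transport genes had a median of 0.00 ± 0.07 (percentile 53.4) with 0 of 32 called. Dync2h1 read 0.35 ± 0.22 on its brightest probe, and from -0.51 to 0.50 over its 6 probes. Tctex1d2 read -0.32 ± 0.17. Basal body, transition zone and BBSome genes had a median of -0.03 ± 0.05 (percentile 15.2) with 0 of 55 called. That list lay at percentile 81.5 on array 1 alone and 3.5 on array 2 alone. Among its 36 members brighter than the median of all genes it read -0.037, at percentile 9.35. Cby1 read -0.36 ± 0.26 and Cep164 -0.35 ± 0.01.

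**Figure D2:**
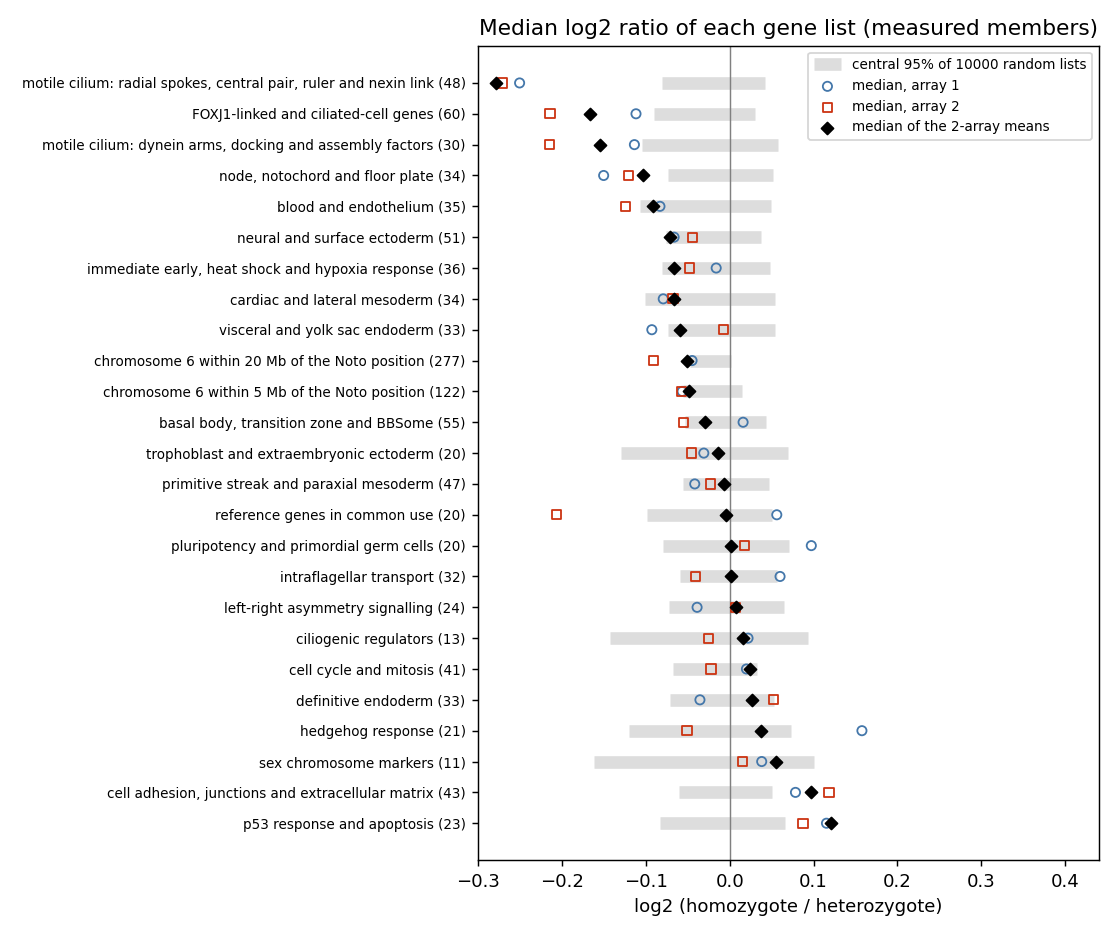
Median log2 ratio of homozygote over heterozygote (x axis) of each gene list (y axis, number of measured members in parentheses), for array 1, for array 2 and for the 2-array means, with a grey bar for the central 95% of medians of 10000 random lists matched on brightness. The 3 motile cilium and FOXJ1-linked lists lie at -0.28, -0.17 and -0.15, and the adhesion and p53 lists at 0.10 and 0.12.

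Node, notochord and floor plate genes went both ways, more often below 0. The list's median was -0.10 ± 0.02, at percentile 0.36, and 1 of 34 measured members, Tppp3, was lower. Ratios lay below 0 on both arrays for 17 members and above 0 on both for 5. Gsc (-0.66 ± 0.20), Foxd4 (-0.57 ± 0.09) and Shh (-0.44 ± 0.07) had ratios below 0 on both arrays. The notochord factor T (brachyury), at 0.33 ± 0.02, and the BMP antagonist Chrd, at 0.08 ± 0.03, had ratios above 0 on both arrays, and Foxa2 read 0.10 ± 0.29. None of these 6 met the size rule. With median centring in place of loess, the node list's median was 0.03 where that of all measured genes was 0.12.

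Among left-right signalling genes, Lefty2 was higher (0.82 ± 0.25; chromosome 1, 182734521 to 182734580) and no other of the 24 measured members was called. Its neighbour Lefty1, the midline inhibitor, read -0.51 ± 0.20. Nodal (-0.03 ± 0.05) and its antagonist Dand5 (-0.09 ± 0.05), both made in the perinodal crown cells, had ratios near 0. The brightest probe of the cation channel gene Pkd2 read 0.04 ± 0.41, with opposite signs on the 2 arrays. Its other measured probe read -1.36 and passed the rule. The list's median was 0.01 ± 0.03, at percentile 62.8. Hedgehog response genes had a median of 0.04 ± 0.15 (percentile 88.1) and 0 of 21 called, with Pax9 at -0.43 ± 0.14 and Pax1 at 0.36 ± 0.13. That list lay at percentile 99.45 on array 1 alone and 40.8 on array 2 alone. Ratios lay below 0 on both arrays for 5 members and above 0 on both for 6. Ptch1 (-0.26 ± 0.07) and Gli1 (-0.12 ± 0.12), chosen after their values were seen, were among the 5.

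**Figure D3:**
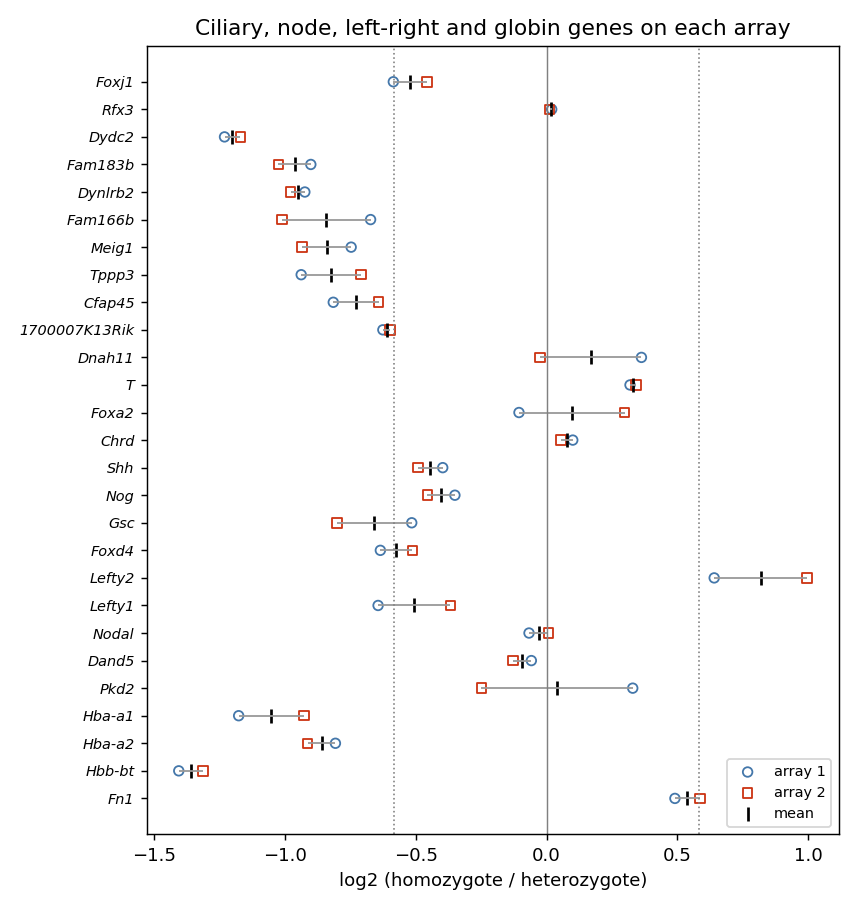
Log2 ratio of homozygote over heterozygote (x axis) of 27 ciliary, node, left-right, globin and matrix genes (y axis) on array 1 (circles), array 2 (squares) and on average (bars); dotted lines mark 1.5-fold. Foxj1 lies at -0.52, the called ciliary genes between -0.61 and -1.20, and Lefty2 at 0.82.

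Adult globins were lower among markers of other tissues, while other genes of red blood cells were not called. The adult beta globin Hbb-bt was lower at -1.36 ± 0.07, with ratios from -0.51 to -1.36 on its 4 measured probes, and the alpha globins Hba-a1 (-1.05 ± 0.18) and Hba-a2 (-0.86 ± 0.08) were lower as well, though Hba-a2 missed the rule on array 1 with median centring (-0.67). The embryonic beta globins Hbb-bh1 and Hbb-y read -0.20 ± 0.03 and -0.44 ± 0.12, and the erythroid genes Alas2, Gata1, Klf1 and Epor read -0.09, 0.21, -0.07 and -0.04. These 6 were chosen after their values were seen. Both embryonic globins were dim, with a mean log2 brightness of 7.3 and 8.1 against 10.9 to 12.1 for the adult globins. In the homozygote they were well above background on 1 of the 2 arrays, so their ratios cannot be compared in size with those of the adult globins. The blood and endothelium list had a median of -0.09 ± 0.03 (percentile 5.47), and these alpha globins were the 2 called of 35. The other lists of germ layers and tissues had medians from -0.07 to 0.03. Among genes brighter than the median of all measured genes, the medians of cardiac (-0.19, 11 genes), trophoblast (-0.17, 8 genes) and neural (-0.15, 26 genes) lists were as low as those of the radial spoke (-0.13, 16 genes) and FOXJ1-linked (-0.14, 16 genes) lists and lower than that of dynein arms (-0.058). In streak and paraxial mesoderm (-0.01 ± 0.01, percentile 48.3), Meox1, a somite factor, was the 1 lower of 47 (-0.62 ± 0.04) but missed the rule with median centring (-0.41) and the mean of probes (-0.59, short on array 2), and Cdx1 read -0.54 ± 0.30. In cardiac and lateral mesoderm (-0.07 ± 0.01, percentile 12.98), Nppa was the 1 lower of 34 (-0.61 ± 0.03) but missed the rule with no background correction (-0.58) and median centring (-0.59, short on array 1), and Myh6 read 0.48 ± 0.06 and Hand1 -0.33 ± 0.16. No member was called in neural and surface ectoderm (-0.07 ± 0.02, percentile 3.77, but 9.1 on array 1 alone and 37.6 on array 2 alone, with Zic2 -0.64 ± 0.32 and Utf1 0.49 ± 0.53), definitive endoderm (0.03 ± 0.06, percentile 86.9, with Foxa3 -0.51 ± 0.02 and Cxcr4 -0.43 ± 0.31, its other probe 0.06) or visceral and yolk sac endoderm (-0.06 ± 0.06, percentile 6.31, with Lrp2 0.40 ± 0.12 and Fgg -0.37 ± 0.17). The same held for trophoblast (-0.01 ± 0.01, percentile 58.3; Plet1 -0.53 ± 0.18, Prl3d1 0.36 ± 0.09) and for pluripotency and germ cell genes (0.00 ± 0.06, percentile 55.7; Utf1 and T as above).

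Genes of adhesion, junctions and extracellular matrix had a median of 0.10 ± 0.03, above 9999 of 10000 random lists, with 0 of 43 called and 23 above 0 on both arrays. Fibronectin, Fn1, read 0.54 ± 0.07 and the tight junction gene Cldn4 0.40 ± 0.26. The 3 other Fn1 probes read 0.71, 0.62 and -0.77, and those at 0.71 and 0.62 passed the rule. Genes of the p53 response and apoptosis had a median of 0.12 ± 0.02, above 9996 of the random lists, with 0 of 23 called; Zmat3 read 0.30 ± 0.13 and Fas -0.30 ± 0.25. Immediate early, heat shock and hypoxia genes had a median of -0.07 ± 0.02 (percentile 5.99), but of -0.016 on array 1 alone (percentile 36.1) and -0.048 on array 2 alone (percentile 36.8). The heat shock gene Hspa1a was the 1 lower of 36 (-0.80 ± 0.15, with its other probes at -0.76, -0.50 and -0.13). Hspa1a missed the rule with median centring (-0.63, short on array 1) and the mean of probes (-0.55), while Junb read -0.75 ± 0.68 and Car9 -0.44 ± 0.21. Cell cycle genes (0.02 ± 0.03, percentile 94.9) had 0 of 41 called, with Cdkn1b at -0.59 ± 0.28 (its other probe at 0.03) and Cenpe at 0.47 ± 0.23.

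Xist, transcribed from the inactive X chromosome, read -0.73 ± 0.24 and was not called by its brightest probe. Its 4 probes read -0.73, -0.71, -0.51 and -0.29, all below 0 on both arrays, and that at -0.71 passed the rule. The Y-linked genes Eif2s3y (0.33 ± 0.48), Uty (0.31 ± 0.40), Kdm5d (0.19 ± 0.38) and Ddx3y (0.18 ± 0.23), the last 3 chosen after their values were seen, had means above 0 that were smaller than their spread over arrays. The median of all sex chromosome markers, 0.06 ± 0.02 (percentile 88.7) with 0 of 11 called, averages X-linked and Y-linked genes. Reference genes in common use had a median of 0.00 ± 0.19 (percentile 68.7) and 0 of 20 called, but of 0.06 on array 1 and -0.21 on array 2; Pgk1 read -0.27 ± 0.50. Within 5 Mb of the Noto position on chromosome 6, a window set for genes near the targeted allele, 3 of 122 measured genes were lower and the median was -0.05 ± 0.00 (percentile 5.64). Within 20 Mb, 11 of 277 were lower with a median of -0.05 ± 0.03 (percentile 1.28).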

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

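The settings limited to brighter genes, or without unnamed transcripts and 5 gene families, were chosen after seeing the data. No paired analysis was possible because the results come from no test; each value is already a ratio of both genotypes within an array, and the shared replicate numbers name the 2 arrays of 1 RNA pool per genotype. What limits the values is 1 pool per genotype, a technical pair of arrays, compressed ratios and dim probes: 4.07% of genes dimmer than the median were lower, against 0.635% of brighter ones. The 33 called genes named by the fixed rule kept their sign under no background correction, the software's log ratios, the value table, median centring and the mean of probes, and 30, 33, 32, 20 and 27 of them still passed the size rule. Under these 5 settings, 102 values of single genes named by that rule, called or not, moved by more than the SD over arrays, 298 did not, and no called one changed sign. The cause of the shifts below was not tested unless stated.

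Counts of higher, lower and all called genes were 101, 713 and 814 with the software's processed log ratios and 82, 690 and 772 with the value table. Each array alone, with fewer values to pass, gave 113 to 124 higher, 644 to 945 lower and 768 to 1058 together. Requiring 2-fold on each array lowered them by construction, to 2, 94 and 96. Requiring a mean of 2-fold gave 2, 172 and 174, of which 171 were called before. Leaving array 2 unturned gave 10, 4 and 14. Genes brighter than the median alone gave 2, 59 and 61, and leaving out unnamed transcripts and 5 gene families gave 140 lower and 148 together. No background correction, median centring, the mean of probes and both other filters on dim probes left all 3 counts within 1.5 times of the reported ones. Similar counts did not mean the same genes with median centring: of its 381 called genes, 307 were among the 448 called before. With the mean of probes, 412 of 418 were.

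Median centring without loess left the median of all measured genes at 0.12, and list medians became 0.10 (ciliogenic regulators), -0.14 (radial spokes), 0.21 (intraflagellar transport), 0.16 (basal body), 0.20 (left-right), 0.035 (node), 0.30 (p53) and 0.28 (adhesion). The mean of probes gave -0.065 for ciliogenic regulators, -0.24 for radial spokes and 0.15 for p53. Among genes brighter than the median, ciliogenic regulators read -0.026, dynein arms -0.058 and radial spokes -0.13, beside -0.19 for cardiac, -0.17 for trophoblast, -0.15 for neural and -0.14 for immediate early genes (percentiles 0, 0.65, 0 and 0.05). With no filter on dim probes, radial spokes read -0.24, dynein arms -0.10, FOXJ1-linked genes -0.10 and node genes -0.073. The software's log ratios gave -0.056 for node genes and 0.15 for p53, and the value table -0.030 for left-right and -0.073 for node genes. Each array alone gave -0.025 to 0.022 for ciliogenic regulators, -0.27 to -0.25 for radial spokes, -0.039 to 0.0069 for left-right, -0.15 to -0.12 for node genes and 0.087 to 0.12 for p53. Over the 11 settings run for these lists, the percentile among 2000 random lists reached at most 9.0 for dynein arms, 0.25 for radial spokes, 0.65 for FOXJ1-linked genes and 5.40 for node genes, and at least 97.3 for p53 and 99.5 for adhesion. The members of the 5 families that were not called had medians of -0.37 to -0.14 under the other normalizations, the mean of probes and single arrays. Medians of the remaining lists (other tissues, hedgehog, cell cycle, stress, sex chromosome and reference genes) moved 12 times under median centring (11 upwards, 1 down) and 37 times under all other settings (16 upwards, 21 down).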

Other observations

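The genes of this paragraph were named, and the tests on genomic DNA or unspliced transcripts chosen, after the results were seen. Outside the fixed lists, lower genes included 8 linked to motile cilia, picked from the calls, with no count of such genes that were not lower: Zfp474 (-1.08 ± 0.07), Odf3b (-1.03 ± 0.02), Lrrc71 (-1.02 ± 0.31), Ccdc153 (-0.91 ± 0.08), Cibar2 (-0.82 ± 0.02), the tubulin polyglutamylase gene Ttll6 (-0.75 ± 0.20), Akap14 (-0.73 ± 0.09) and Efcab10 (-0.64 ± 0.07). The secreted protein gene Wfdc2 (-0.84 ± 0.02) and the metallothioneins Mt1 (-0.82 ± 0.09) and Mt2 (-0.85 ± 0.16) were lower as well. The notochord gene Nog read -0.40 ± 0.07.

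The 448 called genes are nearly all lower in the homozygote and mostly dim. Lower calls were made in 11.1% of 370 genes of families read mainly in sensory neurons, B cells, hair follicles or testis. The share was 6.70% of 3821 unnamed transcripts and 0.973% of the other 14388 genes. These shares are not matched on brightness. Among genes brighter than the median of the measured genes, 2.96% of 846 unnamed transcripts and 0.403% of 8439 other genes were lower. Dye bias is argued against by the 14 genes that an unturned array 2 gives. Within 20 Mb of the Noto position lay 2.49% of called genes and 1.50% of measured genes, so the window holds somewhat more than its share. By the bound set beforehand, this counted against a chromosome 6 segment as the source of most calls. With only 277 measured genes in the window, that result could hardly have come out otherwise. An effect of such a segment on genes inside the window stays open: 11 of the 277 were lower, with the list's median at percentile 1.28. Unequal visceral endoderm, blood or heart tissue, as the source of the calls as a whole, is argued against by 3 list medians of which the farthest from 0 was -0.092. This assumes that such tissue moves its genes together by about 1.5-fold, a size set beforehand. The medians fell short of that by more than their members' SD (0.16 to 0.29), a comparison that was not planned. A smaller imbalance, or one of blood without endothelium, is not excluded, and the adult globins stay open. Family members that were not called themselves had a median of -0.23 over 329 genes. That lay below all 10000 random lists of equally bright genes not called. It met the bound written for genomic DNA or unspliced transcripts in the heterozygote's labelled material. The families were chosen after the calls were seen, and their other members come from the same arrays, so the shift is not independent evidence. It is also not specific to such material, because which part of the gene a probe covers was not examined. The protocol includes a DNase step, and keratin-associated genes alone lay at percentile 29.1. Whether such material accounts for dim lower calls therefore cannot be decided. An effect of the Noto genotype on these genes stays open, as untested.

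The 138 measured genes of the 3 motile cilium and FOXJ1-linked lists had a median of -0.17, and the 11 called ones, all lower, a median of -0.82. Genomic DNA or unspliced transcripts cannot be told apart from another cause. Members brighter (-0.11, 42 genes) and dimmer (-0.21, 96 genes) than the median of all genes were each set against equally bright named genes outside the 5 families. Both medians lay below all 10000 random lists. By the bound written for this test, after the results were seen, that counted against genomic DNA or unspliced transcripts. This bound was set aside, because the families also lay below equally bright genes, and cardiac, trophoblast and neural lists were shifted as far among brighter genes. Fewer node and notochord cells in the homozygous pool cannot be told apart from lower expression per cell: the median of T, Shh, Chrd, Foxa2 and Nog was 0.078, but it averages members that go both ways, Shh and Nog at -0.44 and -0.40 against T at 0.33. By the bound set beforehand, that median of 0.078 counted against fewer such cells. The bound was set aside, because the members go both ways and streak and endoderm in the same pieces also express T and Foxa2. An effect of the Noto genotype on ciliary genes stays open as untested, and Foxj1, at -0.52 (-0.31 with median centring), was itself not called.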
